A study of Lupinus albus with 12 samples.

How the data were processed

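Root RNA was measured in 12 white lupin (Lupinus albus, cultivar Amiga) plants grown in hydroponic Hoagland solution. Sucrose was added to the solution to 10 mM, and root tip sections were taken from untreated plants at 0 min and from treated plants after 20, 40 and 80 min, with 3 plants in each of the 4 groups. Each library is 1 plant, so the replicates are separate plants. All libraries were sequenced on a single flow cell lane with a strand-marking kit for polyadenylated RNA, per the labels' protocols.

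The deposited table holds 33388 genes. Its read counts per gene and library are whole numbers that were not normalized, per the file headers and the values. The table also gives the authors' FPKM per gene and library, which does not sum to a fixed total. The authors deposited a DESeq2 base mean, a signal averaged over the 12 libraries after division by size factors, and for each sucrose time a log2 fold change over control, a p-value and an adjusted p-value, per the file headers. The tools listed are bcl2fastq 2.20, FastQC, Trimmomatic 0.32, HISAT2, StringTie and DESeq2, per the submitters' processing notes, which assign them no role or order. The genome build, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. Counts of members of multigene families, and of overlapping or antisense genes, are uncertain to that extent. The gene identifiers were matched to NCBI's annotation of the assembly CNRS_Lalb_1.0 for gene type and for which genes neighbour each other, and 33388 of 33388 identifiers matched, 33385 as protein coding and 3 as pseudogenes. No coordinates are given because no build is named. Protein names are those of the deposited table.

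Library totals ranged from 35050877 reads (20 min, replicate 2) to 105299704 (80 min, replicate 2). Reads carried no molecular identifiers, so floors based on 3 reads cover counting error only. Genes with too few reads were left out with edgeR's filterByExpr, which kept 28980 genes. The main test was edgeR 4.0.16 (R 4.3.3), with TMM scaling and the robust quasi-likelihood F test (glmQLFit and glmQLFTest), over all 12 libraries in a single fit by group with 8 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and genes were called at an adjusted p below 0.05. CPM values are edgeR's, scaled with the TMM factors. Errors of log2 fold changes are approximate standard errors (SE), the size of the fold change divided by the square root of its F statistic. They are least certain where a group has almost no reads. The common dispersion was 0.449. The comparisons were 20, 40 and 80 min against control, an F test over the 4 time points, and the 3 differences between sucrose times, which do not share the control libraries. DESeq2 1.42.0 was run as a second count test. An adjusted p that DESeq2 did not give was left missing.

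The test and the alternatives were chosen before the data were examined, as were 46 gene lists taken from textbook knowledge of sugar responses, hormones, stress, handling, time of day and root cell types. List members were found by matching words in the protein names, so a list holds the genes whose names match and not a curated pathway. Lists with fewer than 5 tested members were not tested, which left out NAC factors (0 members tested), root cap (4) and sucrose synthesis (3), and 43 lists remained. Each was tested with edgeR's camera on the counts, which asks whether a list's members rank higher or lower than the other genes, with a preset correlation between members of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. The plan allowed camera on log2 values with limma or on counts with edgeR. Both forms had been run before the counts form was taken as the main one, on the ground that the table holds counts, and the form on log2 CPM (limma 3.58.1, prior count 2) is given as an alternative. Camera with a correlation estimated from the data is given beside it. The count of members called is given both over all genes tested and adjusted over the list alone. The adjustment over the list alone does not allow for the number of lists.

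Named genes followed a rule fixed beforehand. At each time against control it took the 5 genes with the largest rise and the 5 with the largest fall among called genes that had a mean of at least 2 CPM, groups that did not overlap and a named function. It added the 2 called members with the smallest p of lists that passed, and the 3 most abundant members of the lists for sucrose cleavage, sugar transport, trehalose phosphate and sugar starvation whatever their test. Genes called at all 3 times, and the 3 genes with the smallest p in each direction between sucrose times, completed it. The C2H2 factor at 20 min, the other genes named among the 26 at 40 min, the genes of the F test, the list members named as called over their list alone, and the per-plant values of low-oxygen and photosynthesis genes were chosen after their values were seen.

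The tests were checked on simulated counts for the real genes, with 200 genes changed at known folds and 28455 genes tested. For 20 min against control, edgeR recovered 2, 19, 29 and 40 of 50 genes changed 2-, 4-, 8- and 16-fold, and DESeq2 recovered 9, 32, 46 and 44. Among unchanged genes of that simulation, edgeR called 1 and DESeq2 117. For 80 min against control with unchanged genes, edgeR called 0 and DESeq2 80. In the simulated lists for 40 min against control, a list of 100 genes shifted by 1 on the log2 scale had a camera p of 5.08e-29 and an unshifted list a p of 0.594. The simulated genes were drawn independently, so this check does not cover lists whose members vary together.

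Comparisons against control share 3 libraries, so correlations and overlaps between them were set beside 40 simulations of unchanged groups. The 3 control libraries cannot be split into parts of at least 2, so part of any excess may come from the shared controls. Alternatives covered DESeq2's size factors, no filter and a stricter filter (mean of at least 5 CPM), only the groups compared, the replicate number as a block, sample-quality weights, a minimum log2 fold change of 1, DESeq2, and leaving out each of the 12 libraries in turn. Added after the data were seen were limma voom without weights, edgeR's quasi-likelihood test with adjusted deviances, genes with 0 reads in any library left out, leaving out 2 libraries that stood apart, and the list tests between sucrose times. Settings for FPKM that had been listed beforehand were not run, since the table holds counts.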

Results

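Roots of white lupin, a legume, were sampled before and after sucrose was added to the nutrient solution, to find which transcripts respond to sucrose as a signal. The 12 libraries come from 4 groups of 3 plants each: untreated controls at 0 min, and plants exposed to 10 mM sucrose for 20, 40 or 80 min. Control libraries held 54369867, 58906006 and 63481050 reads. The libraries held 71789245, 35050877 and 81816759 reads at 20 min, 60412399, 65775749 and 77259779 at 40 min, and 85012891, 105299704 and 65512124 at 80 min. Controls were taken at 0 min only, so time since handling and time of day ran together with the time of exposure.

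Plants of the same group differed in some transcripts of the low-oxygen response. Alcohol dehydrogenase 1 (Lalb_Chr23g0271341), which regenerates NAD+ in fermentation, stood at 23820 and 15680 CPM in replicates 1 and 3 at 20 min and at 902 CPM in replicate 2, against 3539, 2758 and 1833 CPM in the controls. A hypoxia induced protein (Lalb_Chr04g0250311) stood at 144 and 70.1 CPM in the same 2 plants and at 0 in the other, against 2.17, 1.44 and 0.801 CPM in the controls. A non-symbiotic hemoglobin (Lalb_Chr01g0002841) of the same response did not set replicate 2 apart, with 182, 184 and 301 CPM at 20 min against 429, 645 and 364 CPM in the controls. The RuBisCO small subunit (Lalb_Chr13g0300171), a part of the carbon-fixing enzyme of leaves, showed 525, 33.4 and 426 CPM at 20 min, against 219, 225 and 90.2 CPM in the controls. On the first principal component of log2 CPM (18.8% of the variance), 20 min replicate 2 and 80 min replicate 3 lay at 156 and 108, while 80 min replicates 1 and 2 lay at -145 and -129. The 40 min replicates 1, 2 and 3 lay at -20.05, 85.7 and -10.7, and controls between -34.8 and 33.5.

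**Figure D1:**
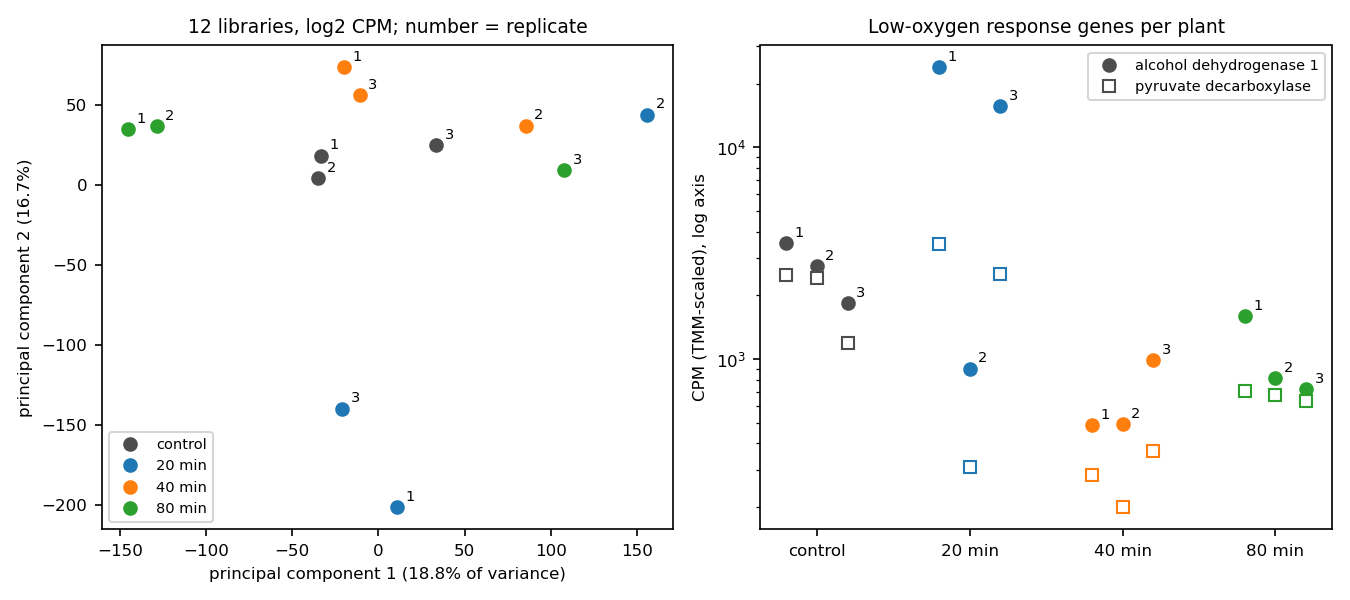
Left, the 12 libraries on the first and second principal components of log2 CPM (18.8% and 16.7% of the variance), coloured by group and numbered by replicate. Right, CPM of alcohol dehydrogenase 1 (filled) and a pyruvate decarboxylase (open squares) in each plant on a log axis. At 20 min, alcohol dehydrogenase 1 stood at 23820, 902 and 15680 CPM in replicates 1, 2 and 3.

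After 20 min, a gene for a SOSEKI protein (Lalb_Chr01g0004581), of a family of polarly located proteins that set cell orientation, rose from 0.0544 ± 0.0635 to 12.9 ± 6.45 CPM (SD, n = 3). The log2 fold change was 7.87 (SE 0.88; edgeR adjusted p = 0.0266), and the 3 control libraries held 2, 7 and 0 of its reads. A gene for a WD40-like protein (Lalb_Chr03g0025941) fell from 108.8 ± 46.9 to 8.94 ± 0.419 CPM (log2 fold change -3.61, SE 0.41, edgeR adjusted p = 0.0278). An AT-hook nuclear-localized protein (Lalb_Chr20g0116811), of a family of DNA-binding proteins, fell from 299 ± 120 to 37.4 ± 2.22 CPM (log2 fold change -3.00, SE 0.31, edgeR adjusted p = 0.0266).

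The other genes that fell at 20 min were a peroxidase (Lalb_Chr02g0143031; log2 fold change -2.67), a thioredoxin-like protein (Lalb_Chr03g0032811; -2.96), a DnaJ domain protein (Lalb_Chr23g0278381; -2.66) and a C2H2 zinc finger factor (Lalb_Chr03g0027711; -2.60). Peroxidases and thioredoxins act on reactive oxygen species and on protein thiols. In all, 7 of 28980 genes were called with edgeR, 1 up and 6 down, 3652 genes had an unadjusted p below 0.05, and DESeq2 called 1206, 606 up and 600 down. The edgeR count was 1014 without 20 min replicate 2, 28 without 80 min replicate 3, 18 without control replicate 3 and 0 to 4 without any single one of the other 9 libraries. Without 20 min replicate 2 and 80 min replicate 3 together, a pair chosen after the values were seen because it stood apart, it was 2404.

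Gene lists fixed beforehand passed in both directions at 20 min. For a list, higher and lower are relative to the other genes and not to a log2 fold change of 0. Over all genes the median log2 fold change against control was 0.065, 0.081 and 0.121 at 20, 40 and 80 min. The meristem and cell cycle list, which holds cyclins and replication factors, was lower (84 of 96 members below 0, median log2 fold change -0.54, camera adjusted p = 2.8e-08; adjusted p = 0.594 with an estimated correlation). Its summed level was 3030, 3853 and 3873 CPM in the 3 plants, against 5327, 4914 and 4116 CPM in the controls. Photosynthesis genes were higher (88 of 102 members above 0, median 0.89, camera adjusted p = 0.000127; adjusted p = 0.636 with an estimated correlation). They summed to 2240 and 1578 CPM in the plants with high alcohol dehydrogenase 1 and to 688 CPM in the other, against 830, 702 and 889 CPM in the controls. Receptor-like kinases (median 0.54, camera adjusted p = 0.0195; adjusted p = 0.704 with an estimated correlation) and brassinosteroid genes (10 of 10 members above 0, median 0.40, camera adjusted p = 0.0195; adjusted p = 0.551 with an estimated correlation) were also higher. Adjusted over the list alone, 1 member of each of these 2 lists was up, among them a BZR1 homolog (Lalb_Chr05g0212971; 0.67), a transcription factor of brassinosteroid signalling. The receptor-like kinase call was lost without control replicate 1 or 20 min replicate 2 (highest camera adjusted p = 0.103), and the brassinosteroid call without control replicate 3 or 20 min replicate 2 (0.0707).

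Lists for sugar use were lower relative to the other genes at 20 min. Sugar transport had 47 of 84 members below 0 (median -0.12, camera adjusted p = 0.0106; adjusted p = 0.594 with an estimated correlation), although its mean was 0.06. Sucrose cleavage (median -0.30, camera adjusted p = 0.0408; adjusted p = 0.594 with an estimated correlation) had 1 member down when adjusted over the list alone, a fructokinase (Lalb_Chr03g0026071; log2 fold change -1.69), which phosphorylates fructose. Gibberellin genes (median -0.63, camera adjusted p = 0.0237; adjusted p = 0.551 with an estimated correlation) had 1 member up and 2 down adjusted over the list alone, all of them gibberellin regulated proteins. Heat shock proteins (median -0.41, camera adjusted p = 0.0237; adjusted p = 0.594 with an estimated correlation) and ribosomal proteins (282 of 433 members below 0, median -0.19, camera adjusted p = 0.0195; adjusted p = 0.771 with an estimated correlation) were lower, with 0 members called by edgeR, 3 and 23 down at an unadjusted p below 0.05 and 2 and 6 down by DESeq2. Over all genes and in either direction, 3652 of 28980 had an unadjusted p below 0.05, a larger share. Hypoxia genes did not pass (9 of 18 members above 0, median 0.01, camera adjusted p = 0.295). Adjusted over the list alone, 2 of them were down, an alcohol dehydrogenase (Lalb_Chr17g0347481; -1.44) and a hypoxia induced protein (Lalb_Chr02g0148071; -1.71), and 0 up, where 0 were called over all genes by edgeR. Without 20 min replicate 2, edgeR called 4 hypoxia genes over all genes, 3 of them up. Aquaporins made up 5 of the 6 osmotic and dehydration genes down when adjusted over the list alone (camera adjusted p = 0.0518). The largest log2 fold change among these 5 was -2.37 (Lalb_Chr25g0289111). The sucrose cleavage call was lost in 10 of 12 fits without a single library, all but those without control replicate 2 or 40 min replicate 3 (highest camera adjusted p = 0.112). Sugar transport was lost without control replicate 3 or 20 min replicate 1 (0.0657), ribosomal proteins without control replicate 1 or 20 min replicate 2 (0.604), and gibberellin without control replicate 3, 20 min replicate 2 or 80 min replicate 1 (0.127). Heat shock proteins were lost without control replicates 1 or 3 or 20 min replicates 1 or 2 (0.105). In all, 9 of 43 lists passed at 20 min, against 15 without control replicate 2, 14 without 20 min replicate 3, 4 without control replicate 3 and 4 without 20 min replicate 2.

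After 40 min, genes of starch breakdown and of abscisic acid turnover were called lower than in the controls. Beta-amylases release maltose from starch: Lalb_Chr20g0118131 fell from 369 ± 117 to 31.6 ± 5.10 CPM (SD, n = 3; log2 fold change -3.55, SE 0.42, edgeR adjusted p = 0.0217), and Lalb_Chr18g0055731 from 137 ± 38.6 to 18.0 ± 4.74 CPM (-2.92, SE 0.39, edgeR adjusted p = 0.0304). An abscisic acid 8'-hydroxylase (Lalb_Chr05g0215161), which inactivates that hormone, fell from 568 ± 216 to 47.1 ± 6.398 CPM (-3.59, SE 0.47, edgeR adjusted p = 0.0300). The beta-amylases and this hydroxylase were already lower at 20 min, called over their list alone and not over all genes. Their log2 fold changes there were -3.00, -2.64 and -2.11 (edgeR adjusted p over all genes = 0.0548, 0.0743 and 0.162). At 40 against 20 min edgeR called 0 genes. A bHLH transcription factor (Lalb_Chr25g0283231) fell from 211 ± 96.1 to 9.34 ± 5.21 CPM (-4.50, SE 0.56, edgeR adjusted p = 0.0266). The SOSEKI gene again rose, to 15.9 ± 3.78 CPM (8.16, SE 0.89, edgeR adjusted p = 0.0167), and was the only gene called up.

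Regulators and enzymes of other kinds were among the genes that fell at 40 min. They included the WD40-like gene (log2 fold change -4.47), an ACT domain repeat protein (Lalb_Chr09g0324571; -3.62), a phloem protein (Lalb_Chr01g0018441; -2.10), the AT-hook gene (-2.90) and the thioredoxin-like gene (-3.49). A beta-carotene 3-hydroxylase (Lalb_Chr03g0034851; -1.91), which makes xanthophylls upstream of abscisic acid, a phosphoinositide phospholipase C (Lalb_Chr23g0265071; -1.76) and a phosphatidylinositol 4-kinase (Lalb_Chr04g0254431; -1.33) fell, as did a MAP kinase kinase kinase (Lalb_Chr10g0103451; -3.18) and a cysteine dioxygenase (Lalb_Chr06g0175451; -2.92). A WD40/YVTN repeat gene (Lalb_Chr22g0355491) had 0 reads in all 3 libraries at 40 min against 2.83 ± 1.31 CPM in the controls, at least 64.8-fold lower at a floor of 3 reads per library. In all, edgeR called 26 genes, 1 up and 25 down, 1736 genes had an unadjusted p below 0.05, and DESeq2 called 566, 125 up and 441 down. For most of the 25 genes control replicate 3 was the lowest of the controls. They may thus vary together between untreated plants and need not be separate responses. The edgeR count was 156 without 20 min replicate 2, 58 without control replicate 3, 32 without 80 min replicate 3 and 0 to 11 without any single one of the other 9 libraries. A fit of the 6 libraries compared called 1 gene, which was not among the 26.

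**Figure D2:**
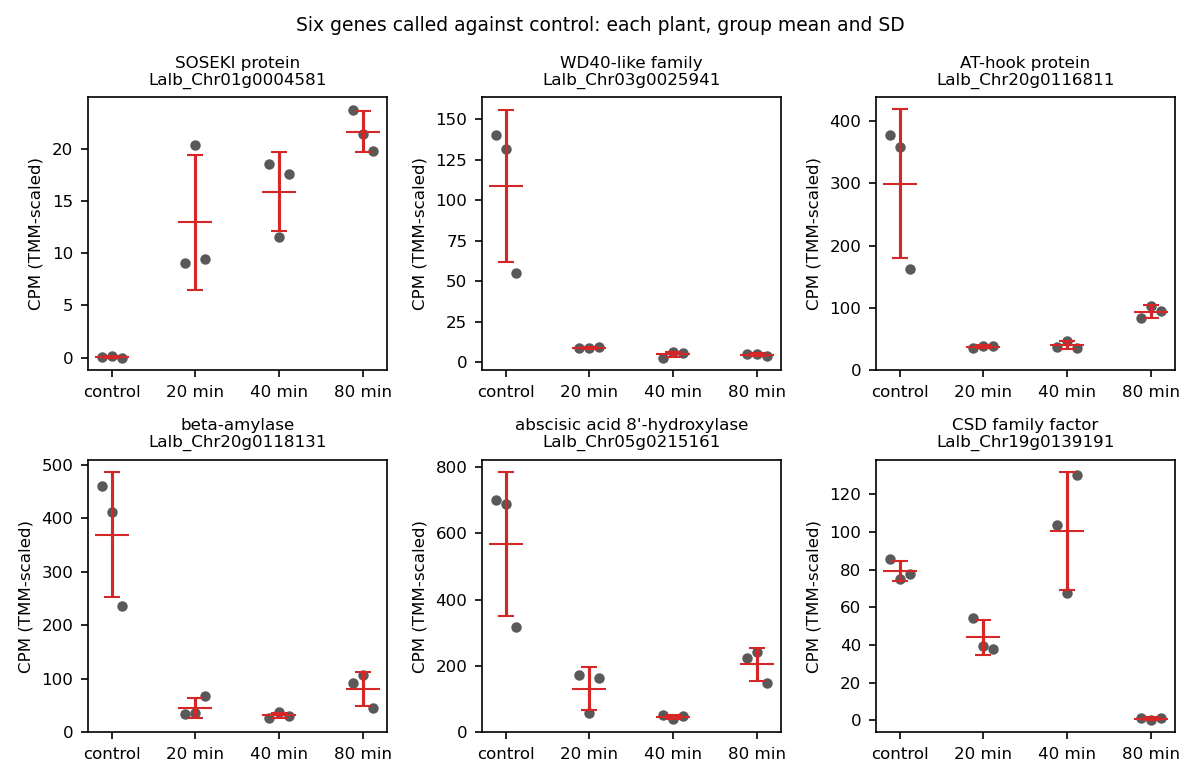
CPM of 6 genes called against control in each of the 12 plants (grey points), with the mean and SD of each group of 3 (red), on linear axes. The SOSEKI gene goes from a mean of 0.0544 CPM in the controls to 12.9, 15.9 and 21.6 CPM, and the WD40-like gene from 108.8 to 8.94, 4.90 and 4.77 CPM.

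Lists for sugar signalling and low oxygen were lower at 40 min. Hypoxia genes had 11 of 18 members below 0 (median log2 fold change -0.68, camera adjusted p = 2.8e-05; adjusted p = 0.110 with an estimated correlation). Adjusted over the list alone, 4 were down, among them a pyruvate decarboxylase (Lalb_Chr01g0023181; -2.84) and a non-symbiotic hemoglobin (Lalb_Chr01g0002841; -1.58). Trehalose phosphate genes were lower (median -0.31, camera adjusted p = 0.0104; adjusted p = 0.110 with an estimated correlation), with 3 trehalose 6-phosphate phosphatases down adjusted over the list alone, from -2.47 (Lalb_Chr08g0240471) to -3.24 (Lalb_Chr12g0203741). These enzymes remove the phosphate from trehalose 6-phosphate, a signal of sucrose status. SnRK1 and TOR signalling genes were lower (median -0.28, camera adjusted p = 0.0104; adjusted p = 0.360 with an estimated correlation), with 3 FLZ zinc finger proteins, partners of the SnRK1 kinase, down adjusted over the list alone. Abscisic acid genes were lower by camera (adjusted p = 0.0134; adjusted p = 0.110 with an estimated correlation) although their median was 0.04, and 3 of the 5 members down adjusted over the list alone were 8'-hydroxylases. The call of abscisic acid was lost without 40 min replicate 1 (highest camera adjusted p = 0.0798), that of trehalose phosphate without 40 min replicates 1 or 3 (0.0540), and that of SnRK1 and TOR signalling without control replicate 1 or 40 min replicate 1 (0.0616).

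Starch, phloem and ethylene lists were lower at 40 min, and ribosomal and cell cycle lists higher. Starch metabolism (median -0.11, camera adjusted p = 0.0393; adjusted p = 0.364 with an estimated correlation) had the 2 beta-amylases down, and phloem (median -0.22, camera adjusted p = 0.0261; adjusted p = 0.364 with an estimated correlation) had 3 phloem proteins down, adjusted over the list alone. Ethylene genes were lower (65 of 110 members below 0, median -0.30, camera adjusted p = 0.00122; adjusted p = 0.364 with an estimated correlation) with 0 members called by edgeR, 15 down at an unadjusted p below 0.05 and 6 down by DESeq2. Among all genes tested, 1736 of 28980 had such a p in either direction. Ribosomal proteins were higher (360 of 433 members above 0, median 0.35, camera adjusted p = 2.8e-05; adjusted p = 0.878 with an estimated correlation). They summed to 63850, 35670 and 53930 CPM against 43730, 39160 and 36790 CPM in the controls. Cell cycle genes were higher (median 0.25, camera adjusted p = 0.0393; adjusted p = 0.985 with an estimated correlation), with summed levels of 6630, 4397 and 5611 CPM. Without 40 min replicate 1, hypoxia was the 1 list of these 9 that passed, and the ribosomal list had a camera adjusted p of 0.167 (range over the alternatives 6.2e-11 to 0.878). The cell cycle call was lost in 6 of 12 fits, without control replicate 3, 20 min replicate 2, 40 min replicates 1 or 3 or 80 min replicates 1 or 2 (highest 0.853). Starch metabolism was also lost in 6, without control replicate 1, 20 min replicate 2, any 40 min library or 80 min replicate 1 (highest 0.397), and phloem without control replicate 1 or 40 min replicates 1 or 3 (0.190). Ethylene was lost without 40 min replicate 1 (0.0560). Camera on log2 CPM passed 3 lists, ribosomal proteins, hypoxia and ethylene.

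After 80 min, a gene for a CSD family transcription factor (Lalb_Chr19g0139191) fell from 79.3 ± 5.46 to 0.895 ± 0.680 CPM (SD, n = 3; log2 fold change -6.47, SE 0.74, edgeR adjusted p = 0.0450). CSD names cold shock domain proteins, which bind nucleic acids. Its level was 44.0 ± 9.12 CPM at 20 min and 100.5 ± 31.2 CPM at 40 min. The SOSEKI gene rose to 21.6 ± 1.98 CPM (8.61, SE 0.90, edgeR adjusted p = 0.0294), and the WD40-like gene fell to 4.77 ± 0.938 CPM (-4.51, SE 0.43, edgeR adjusted p = 0.0259). These were the 3 genes called with edgeR, 1 up and 2 down, while 2873 had an unadjusted p below 0.05 and DESeq2 called 860, 270 up and 590 down. The edgeR count was 462 without 80 min replicate 3, 18 without 20 min replicate 2, 16 without control replicate 3 and 0 to 3 without any single one of the other 9 libraries. Without the 2 libraries that stood apart it was 1631.

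More lists passed at 80 min than at the earlier times, 2 higher and 16 lower. Adjusted over all genes, edgeR called 0 members of any list at 80 min against control. Ribosomal proteins were higher (376 of 433 members above 0, median log2 fold change 0.55, camera adjusted p = 2.7e-09; adjusted p = 0.569 with an estimated correlation), and so were cell cycle genes (79 of 96 members above 0, median 0.41, camera adjusted p = 0.00863; adjusted p = 0.664 with an estimated correlation). Ribosomal protein transcripts summed to 72220 and 71100 CPM in replicates 1 and 2 and to 31920 CPM in replicate 3, which lay below the 3 controls. The cell cycle list was at 6566 and 6822 CPM in the first 2 plants and 4541 CPM in replicate 3, and its call was lost without control replicate 3 (camera adjusted p = 0.314), 80 min replicate 1 (0.334) or 80 min replicate 2 (0.304), with a range over the alternatives of 9.9e-06 to 0.664.

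Redox, nitrogen and low-oxygen lists were lower at 80 min. Oxidative stress and detoxification genes had 13 of 241 members down adjusted over the list alone, 8 of them peroxidases (median log2 fold change -0.04, camera adjusted p = 0.00863; adjusted p = 0.287 with an estimated correlation). Among these peroxidases Lalb_Chr04g0251831 had a log2 fold change of -3.19 and Lalb_Chr18g0052481 of -1.81. Nitrate and ammonium assimilation was lower (17 of 21 members below 0, median -0.49, camera adjusted p = 0.00532; adjusted p = 0.287 with an estimated correlation), with an ammonium transporter down adjusted over the list alone (Lalb_Chr07g0184111; -1.72). Hypoxia genes were lower (14 of 18 members below 0, median -0.67, camera adjusted p = 0.00818; adjusted p = 0.287 with an estimated correlation), with 0 members called by edgeR, 4 down at an unadjusted p below 0.05 and 1 by DESeq2. Sugar starvation markers, genes that sugar depletion induces, were lower (21 of 32 members below 0, median -0.45, camera adjusted p = 0.0144; adjusted p = 0.287 with an estimated correlation). Sugar transport was also lower (median -0.13, mean 0.07, camera adjusted p = 0.0120; adjusted p = 0.431 with an estimated correlation). In both, edgeR called 0 members, with 3 and 14 down at an unadjusted p below 0.05 and 2 and 6 down by DESeq2. Among all genes tested, 2873 of 28980 had such a p in either direction. The oxidative stress and sugar transport calls were lost without control replicate 3 or 80 min replicate 1 (highest camera adjusted p = 0.0876 and 0.165). The starvation marker call was lost without those or control replicate 1 (0.0792), and the hypoxia call without 80 min replicate 3 (0.0775).

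Flavonoid, WRKY, abscisic acid, phloem, receptor-like kinase and cell wall lists also passed downward at 80 min. Flavonoid and phenylpropanoid synthesis was lower (median log2 fold change -0.22, camera adjusted p = 0.00818; adjusted p = 0.461 with an estimated correlation), with a flavanone 3-dioxygenase down adjusted over the list alone (Lalb_Chr25g0288821; -2.58). WRKY factors, which regulate defence genes, had 2 members down adjusted over the list alone (median -0.18, camera adjusted p = 0.00818; adjusted p = 0.597 with an estimated correlation). Abscisic acid genes had 2 (median -0.30, camera adjusted p = 0.0213; adjusted p = 0.287 with an estimated correlation), phloem 2 (median -0.19, camera adjusted p = 0.0357; adjusted p = 0.420 with an estimated correlation) and receptor-like kinases 1 (median -0.20, camera adjusted p = 0.0213; adjusted p = 0.597 with an estimated correlation). The cell wall list passed downward (camera adjusted p = 0.0367; adjusted p = 0.431 with an estimated correlation) with a median of 0.06 and a cellulose synthase down adjusted over the list alone (Lalb_Chr20g0114291; -2.94). Without control replicate 3, 80 min replicate 1 or 80 min replicate 2, the flavonoid, WRKY and receptor-like kinase calls were lost (highest camera adjusted p = 0.371, 0.186 and 0.308). The abscisic acid call was lost without those or 80 min replicate 3 (0.106), and the phloem call without those 4 or control replicate 1 (0.0917). The cell wall call was lost without control replicate 3, 40 min replicates 1 or 2 or 80 min replicates 1 or 3 (0.518).

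Another 5 lists passed downward at 80 min with 0 members called by edgeR, whether adjusted over all genes or over the list alone. They were xylem and secondary wall (median log2 fold change -0.34, camera adjusted p = 0.0120; adjusted p = 0.287 with an estimated correlation), phosphate starvation (-0.13, 0.0190; adjusted p = 0.3499 with an estimated correlation) and glycolysis (-0.17, 0.0275; adjusted p = 0.561 with an estimated correlation), with 6, 15 and 9 members down at an unadjusted p below 0.05 and 0, 6 and 1 by DESeq2. Endodermis and suberin (-0.18, 0.0314; adjusted p = 0.597 with an estimated correlation) and touch and wounding (-0.28, 0.0357; adjusted p = 0.420 with an estimated correlation) had 3 and 7 at an unadjusted p below 0.05 and 2 and 3 by DESeq2. For comparison, 2873 of all 28980 genes had an unadjusted p below 0.05 in either direction. The circadian clock list, a check on time of day, did not pass at 20, 40 or 80 min (camera adjusted p = 0.823, 0.260 and 0.972). Touch and wounding and endodermis were lost without control replicate 3 or 80 min replicates 1 or 2 (highest camera adjusted p = 0.269 and 0.515), endodermis also without 40 min replicate 2. Phosphate starvation was lost without control replicate 3 or any 80 min library (0.210), xylem without control replicate 3 or 80 min replicate 3 (0.208), and glycolysis without control replicate 1 or 80 min replicate 3 (0.786). Of the lists that passed, 4 remained as a count without control replicate 3, 5 without 80 min replicate 1 and 9 without 80 min replicate 2, against 18 with all libraries.

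**Figure D3:**
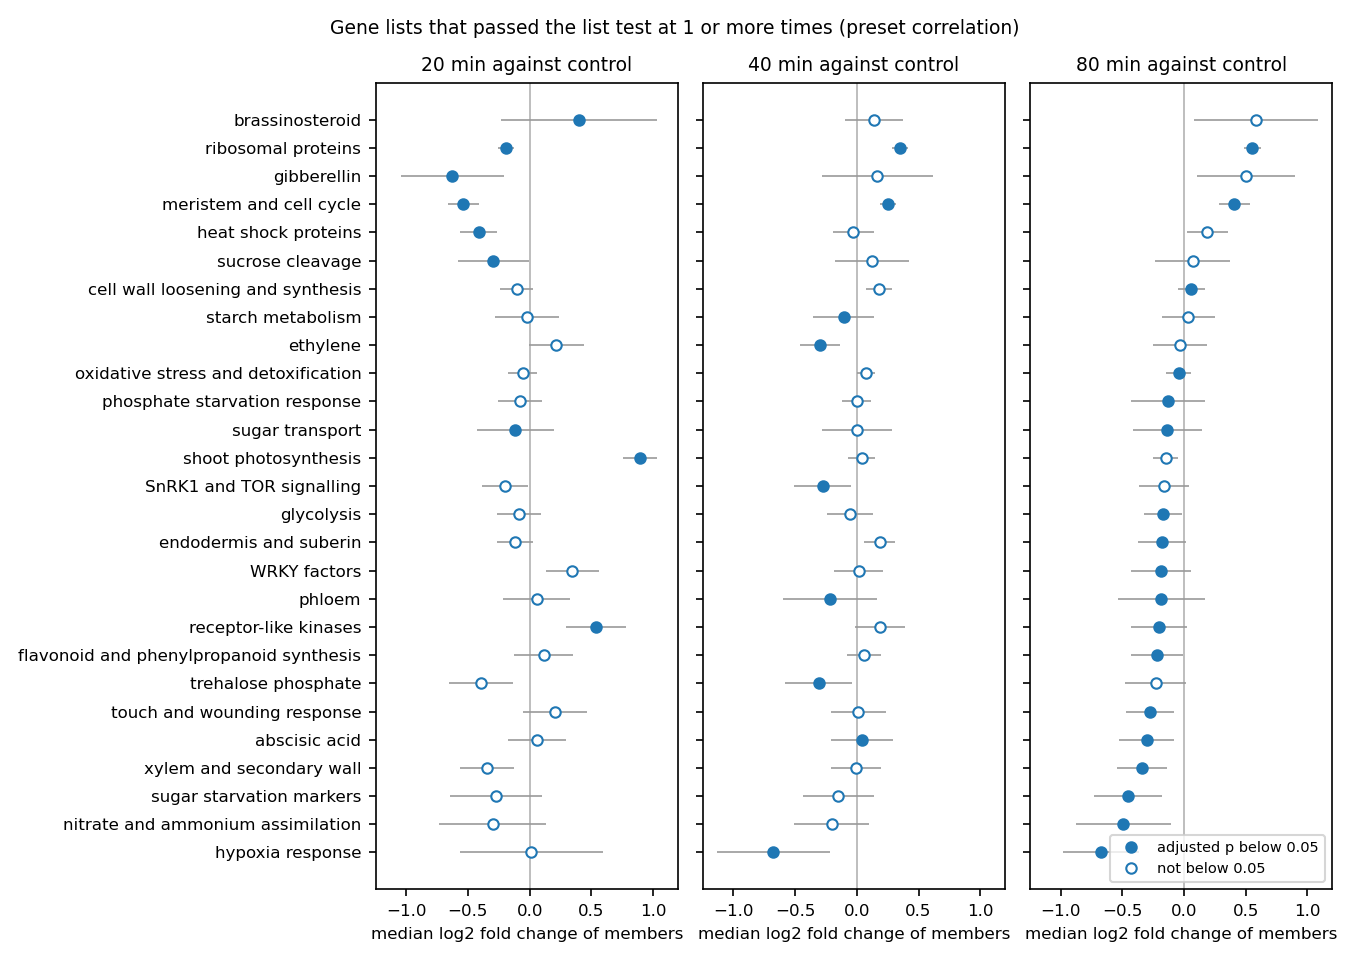
Median log2 fold change of the members of each gene list that passed camera at 1 or more of the 3 times against control, with its standard error (bars); filled circles mark an adjusted p below 0.05 with the preset correlation. Cell cycle genes have medians of -0.54, 0.25 and 0.41 at 20, 40 and 80 min, and ribosomal proteins of -0.19, 0.35 and 0.55.

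Abundant genes of sugar metabolism were followed whatever their test, and edgeR called none of them at any of the 3 times. A sucrose synthase (Lalb_Chr11g0073991), which splits sucrose, averaged 934 ± 195 CPM in the controls and 1267 ± 430, 402 ± 200 and 186 ± 63.6 CPM at 20, 40 and 80 min (SD, n = 3). At 80 min its log2 fold change was -2.33 (SE 0.47, edgeR adjusted p = 0.198), and DESeq2 called it (adjusted p = 0.000166, range over the alternatives 0.000166 to 0.582). A trehalose 6-phosphate phosphatase (Lalb_Chr08g0241961) averaged 174 ± 68.2 CPM in the controls and 23.5 ± 6.38 CPM at 40 min (-2.89, SE 0.58, edgeR adjusted p = 0.165), where DESeq2 called it (DESeq2 adjusted p = 7.6e-05, range 7.6e-05 to 0.677). An asparagine synthetase (Lalb_Chr15g0083001), a marker of sugar starvation, averaged 783 ± 196 CPM in the controls and 141 ± 95.8 CPM at 80 min (-2.47, SE 0.75, edgeR adjusted p = 0.368; DESeq2 adjusted p = 0.0246, range 0.00244 to 0.753). A sugar transporter (Lalb_Chr05g0210921) went from 252 ± 47.9 to 104.6 ± 20.1 CPM at 80 min (-1.27, SE 0.32, edgeR adjusted p = 0.282; DESeq2 adjusted p = 0.0163, range 0.00572 to 0.682). The fructokinase Lalb_Chr22g0352101, at 1268 ± 200 CPM in the controls, had log2 fold changes of 0.21, -0.84 and -0.54 with edgeR adjusted p of 0.894, 0.948 and 0.697.

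The other genes taken by abundance were not called by edgeR at any of the 3 times. A dormancy and auxin associated protein (Lalb_Chr18g0059451), also a marker of sugar starvation, averaged 58.2 ± 22.9 CPM in the controls and 257 ± 359, 702 ± 1084 and 688 ± 941 CPM at 20, 40 and 80 min (SD, n = 3). Its log2 fold changes were 2.14, 3.59 and 3.56 (edgeR adjusted p = 0.627, 0.901 and 0.539; DESeq2 adjusted p = 0.477, 0.273 and 0.190), with adjusted p over the alternatives from 0.387 to 0.991, 0.273 to 1 and 0.190 to 0.800. Single libraries carried these values: 20 min replicate 1 held 44384 of its reads, 40 min replicate 2 131654 and 80 min replicate 3 126154, and without them the log2 fold changes of Lalb_Chr18g0059451 were -0.23, 0.37 and 1.39. The asparagine synthetase Lalb_Chr10g0103401 had -1.77, -1.63 and -1.60 (edgeR adjusted p = 0.495, 0.992 and 0.614), and the sucrose synthase Lalb_Chr07g0181391 had 0.45, -0.27 and -1.19 (0.916, 0.999 and 0.762). At 20 min this asparagine synthetase stood at 475 CPM in replicate 2 and at 13.3 and 27.55 CPM in replicates 1 and 3. Over the alternatives its log2 fold change there ranged from -4.93 to -1.23 (adjusted p 0.00341 to 0.794). Its adjusted p at 80 min ranged from 0.0204 to 0.921. The sugar transporter Lalb_Chr22g0357221 had -1.87, -0.62 and -2.24 (edgeR adjusted p = 0.438, 0.999 and 0.495), and Lalb_Chr09g0327281 had -0.80, 0.10 and -0.66 (0.340, 0.999 and 0.513). At 20 min Lalb_Chr22g0357221 stood at 430 CPM in replicate 2 and at 21.0 and 50.2 CPM in replicates 1 and 3. Over the alternatives its log2 fold change there ranged from -4.18 to -1.35 (adjusted p 0.00385 to 0.755). Its adjusted p at 80 min ranged from 0.00342 to 0.823, and that of Lalb_Chr09g0327281 at 20 min from 0.0123 to 0.727. Trehalose phosphate synthases had -0.06, -0.33 and -0.10 (Lalb_Chr05g0222101; edgeR adjusted p = 0.959, 0.999 and 0.928) and 0.29, 0.17 and 0.01 (Lalb_Chr21g0308741; 0.750, 0.999 and 0.997).

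The SOSEKI gene was up and the WD40-like gene down at all 3 times, the 2 genes called at each time. Simulated unchanged groups that shared simulated controls gave 0 such genes in 40 simulations. Few genes are called where none is changed, so that 0 could hardly have been otherwise. Independent lists of these sizes would share 1.2e-09 up and 3.6e-07 down, a value that ignores the shared controls. Neither figure measures the overlap that shared controls produce among called genes. This overlap was 10 without control replicate 3, 5 without 20 min replicate 2, 5 without 80 min replicate 3, 2 without control replicate 2 and 0 without any single one of the other 8 libraries. Across genes, which are not independent replicates, log2 fold changes at 20 and 40 min had r = 0.484 (simulated 0.503), those at 20 and 80 min r = 0.495 (simulated 0.502) and those at 40 and 80 min r = 0.622 (simulated 0.503). The first 2 values of r lay inside the simulated ranges (0.481 to 0.534 and 0.472 to 0.528), and the third above its range (0.475 to 0.5275). Without 80 min replicate 3 the third was 0.486, for which no simulation was run. The simulated genes were drawn independently with the same spread in every group, so these ranges do not cover genes that vary together. The covariances were 0.894, 0.959 and 1.10, against simulated values of 0.551, 0.547 and 0.547, differences of 0.343, 0.411 and 0.558. A covariance also grows with the spread of fold changes. For 20 min with 40 or 80 min, the difference therefore does not show a shared response. The share of genes with the same sign was 60.3% for 20 and 40 min and 60.6% for 20 and 80 min, below the simulated 66.8% and 66.7%, and 75.3% for 40 and 80 min, above the simulated 66.7%. The controls were too few to split, so part of the covariance may come from the shared libraries.

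Calls of single genes depended on the test and on the libraries in the fit. At 20 min the adjusted p over the alternatives ranged from 2.5e-28 (DESeq2) to 0.211 for the SOSEKI gene. For the WD40-like gene it ranged from 2.0e-14 (DESeq2) to 0.223. Their log2 fold changes stayed between 7.18 and 9.35 and between -4.01 and -3.38. All 36 calls of genes named against control were lost without control replicate 1, without 80 min replicate 1, and in fits of the compared groups alone, and DESeq2 kept all 36.

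Over the 4 time points, the F test called 21 genes, among them the SOSEKI, WD40-like, AT-hook, thioredoxin-like, CSD and beta-amylase genes. It added 3 genes not called at a single time against control. A catechol O-methyltransferase (Lalb_Chr19g0135061) had log2 fold changes of 4.38, -0.88 and -1.68 at 20, 40 and 80 min. An ent-kaurene synthase (Lalb_Chr13g0296671), an early enzyme of gibberellin synthesis, had 0.67, -1.73 and -4.20, and a hydrolase (Lalb_Chr15g0087121) 1.90, -0.43 and -1.97. The 3 had edgeR adjusted p of 0.0341, 0.0341 and 0.0419. In the F test 3873 genes had an unadjusted p below 0.05, and DESeq2 called 2313. The count was 997 without 20 min replicate 2, 532 without 80 min replicate 3, 47 without control replicate 3 and 1 to 5 without any single one of the other 9 libraries.

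Between sucrose times, edgeR called 0 genes. The genes with the smallest p included the CSD factor, with a log2 fold change of -6.81 (SE 0.75, edgeR adjusted p = 0.0897) at 80 against 40 min. An ACC synthase (Lalb_Chr05g0224501), the step that commits to ethylene synthesis, was at 5.96 ± 1.33 CPM at 80 min and 33.2 ± 8.94 CPM at 40 min (-2.48, SE 0.31, edgeR adjusted p = 0.0897), and a peroxidase (Lalb_Chr18g0052481) at 17.9 ± 1.81 and 88.3 ± 32.3 CPM (-2.30, SE 0.28, edgeR adjusted p = 0.0897). At 80 against 20 min, a lipoxygenase (Lalb_Chr24g0396541) had 2.54 (SE 0.41, edgeR adjusted p = 0.130) and the ent-kaurene synthase -4.87 (SE 0.55, edgeR adjusted p = 0.104). A ferritin gene (Lalb_Chr13g0291401), for an iron storage protein, had 0 reads in all 3 libraries at 20 min and 1.03 ± 0.475 CPM at 40 min, at least 18.9-fold higher at the same floor, with an edgeR adjusted p of 0.214.

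Cell cycle and ribosomal protein genes were higher at 40 and 80 min than at 20 min as lists (medians of 0.77 and 0.53 at 40 min, 0.88 and 0.71 at 80 min; camera adjusted p = 1.1e-14, 1.0e-10, 1.6e-15 and 1.6e-15; adjusted p = 0.556, 0.562, 0.679 and 0.679 with an estimated correlation). For single genes between times, 4106, 1307 and 5012 had an unadjusted p below 0.05 at 40 against 20, 80 against 40 and 80 against 20 min, and DESeq2 called 1439, 248 and 2060. Without 20 min replicate 2, edgeR called 1450 genes at 40 against 20 min and 975 at 80 against 20 min. Without 80 min replicate 3 it called 182 at 80 against 40 min and 3541 at 80 against 20 min. Without any other single library it called at most 3, 2 and 5 genes in these comparisons.

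The authors' deposited table, made with DESeq2, has 1205, 569 and 857 genes at an adjusted p below 0.05 at 20, 40 and 80 min. Of the genes called with edgeR, 7 of 7, 26 of 26 and 3 of 3 are also called there in the same direction. The DESeq2 run here shared 1205, 565 and 857 calls with the authors' deposited table. Base means were equal within a relative tolerance of 0.001 for 33388 of 33388 genes. Among the genes called in the authors' deposited table, 220, 141 and 158 had 0 reads in at least 1 library.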

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

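Of the tests weighed here, those on correlation between list members, the 2 libraries that stood apart, exchanged labels, a plant without sucrose, low oxygen, and reads of neighbouring or same-named genes were chosen after the result was seen. The results gathered here are gene lists that differed between 2 sucrose times by a direct camera test of the difference, and each lost its call with an estimated correlation.

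At 40 against 20 min, cell cycle genes (median log2 fold change 0.77, adjusted p = 1.12e-14), ribosomal proteins (0.53, 1.03e-10), sugar transport (0.36, 0.0374), gibberellin (0.76, 0.0374), sucrose cleavage (0.34, 0.0442) and osmotic response (0.24, 0.0442) were higher. Photosynthesis (-0.89, 1.64e-05), ethylene (-0.33, 0.000441), WRKY factors (-0.34, 0.0273) and brassinosteroid (-0.37, 0.0442) were lower. With an estimated correlation the adjusted p was 0.556 to 0.726. Of 12 fits without a single library, osmotic response and brassinosteroid lost their calls in 7 each and sucrose cleavage in 4. Sugar transport and WRKY factors lost theirs in 3 each, gibberellin in 2 and the other lists in 0.

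At 80 against 40 min, ribosomal proteins (median log2 fold change 0.20, adjusted p = 0.0189) and SnRK1 and TOR signalling (0.19, 0.0412) were higher. The ribosomal list turned down without 40 min replicate 2 (adjusted p = 0.627), 80 min replicate 1 (0.952) or 80 min replicate 2 (0.881). Receptor-like kinases (-0.35, 0.000251), flavonoid synthesis (-0.23, 0.00316), WRKY factors (-0.13, 0.00458), defence (-0.09, 0.00652), oxidative stress (-0.02, 0.00652), endodermis (-0.33, 0.00653), phosphate starvation (-0.05, 0.0076), sugar transport (-0.25, 0.0127), xylem (-0.16, 0.0189), cytokinin (-0.11, 0.0189), cell wall (-0.04, 0.0189) and osmotic response (-0.12, 0.0365) were lower. With an estimated correlation the adjusted p was 0.382 to 0.786. Of 12 fits without a single library, osmotic response lost its call in 6. WRKY factors, endodermis, cytokinin and SnRK1 and TOR signalling lost theirs in 3 each. Flavonoid synthesis, sugar transport, xylem and cell wall lost theirs in 2 each, and defence and oxidative stress in 1 each. Receptor-like kinases and phosphate starvation lost theirs in 0.

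At 80 against 20 min, ribosomal proteins (median log2 fold change 0.71, adjusted p = 1.59e-15), cell cycle genes (0.88, 1.59e-15), gibberellin (0.54, 0.00606) and heat shock proteins (0.29, 0.0139) were higher. Photosynthesis (-1.02, 2.37e-06), receptor-like kinases (-0.70, 2.37e-06), WRKY factors (-0.47, 2.69e-06), flavonoid synthesis (-0.47, 0.00689) and ethylene (-0.26, 0.0411) were lower. With an estimated correlation the adjusted p was 0.679 for each. Of 12 fits without a single library, ethylene lost its call in 4, heat shock proteins in 2, flavonoid synthesis in 1 and the other lists in 0.

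The opposite movement of ribosomal and cell cycle genes at 20 and 80 min was set against 4 explanations. Depth was excluded, since the larger adjusted p of the 2 lists was 1.53e-14 with all libraries thinned to the smallest total. The difference between 80 and 20 min remained without the 2 libraries that stood apart. Without both, cell cycle genes had a median of 1.28 (SE 0.153) and ribosomal proteins of 0.85 (SE 0.0855), errors that treat members as independent. With all libraries the medians were 0.88 and 0.71. For 80 min replicate 3 this was no test, since its summed levels of both lists lay below those of 80 min replicates 1 and 2. Leaving it out favoured the difference, and the rise at 80 min was carried by those 2 plants. The fall of ribosomal proteins at 20 min against control was lost without 20 min replicate 2, and also without control replicate 1 (highest camera adjusted p = 0.604). Members that vary together between plants of a group remain possible (adjusted p = 0.679 with an estimated correlation). A smaller share of meristem in the 20 min pieces cannot be told apart from a response to sucrose, since the highest median among xylem, phloem and endodermis lists was -0.000701 (SE 0.209).

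The library of 20 min replicate 2 stood apart from the others of its group. A difference in depth was excluded as the source. With libraries thinned to its total, 14 genes were called at 20 min with it and 1030 without it. An exchange of labels with 80 min replicate 3 predicted a positive mean r with 80 min replicates 1 and 2, and the value was -0.327. Under its own label, however, 80 min replicate 3 also had a negative r with each of them (-0.283 and -0.246). A negative r therefore does not place a library outside the 80 min group, and this exchange was not excluded. An exchange with a plant of another group was not tested. On 96.2% of the 26 genes called at 40 min, the value of 20 min replicate 2 lay nearer to the 40 min mean than to the control mean. On those genes this argues against a plant in the state of the 0 min controls, but their selection was not independent of the library. It is in neither group of that comparison, and none of those calls was lost without it. The spread was pooled over all 12 libraries, however, and without it 156 genes were called at 40 min. The pooled spread favours genes on which it lies near the others of its group, so the share may be lower on other genes. No untreated plant was taken at 20 min, so a plant handled alike but without sucrose remains open. A low-oxygen response in the other 2 plants remains open: without this library 4 of 18 hypoxia genes were called, 3 of them up, which restates the observation that prompted the test.

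The SOSEKI gene was nearly absent in the controls alone. Reads counted for a same-named gene were excluded (controls minus treated -5.25 CPM, SE 5.89). Reads counted for neighbouring genes remain possible, as the 4 neighbours stood 196 CPM higher in the controls (SE 68.8) against a rise of 16.8 CPM. Genes on or off by plant whatever the treatment also remain possible, since 39 of 220 trios of libraries held as many such genes, with 4 in the highest other trio. A response to sucrose was therefore not separated from these.

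With 3 against 3 libraries there are 10 splits, so the share of splits cannot be under 0.05. As many genes as in the real grouping were called in 2 of 10 splits at 20 min (real 7, highest other 7), 1 at 40 min (26, 4) and 1 at 80 min (3, 2). Between times it was 10 of 10 for 40 against 20 min (0, 3), 10 for 80 against 40 min (0, 2) and 10 for 80 against 20 min (0, 2). With DESeq2 it was 1 of 10 at each time (1206, 564; 566, 210; 860, 684), and for lists passing 1 of 10 at each time (9, 6; 9, 6; 18, 12). For the F test 2 of 100 splits held as many genes (real 21, highest other 226, in a grouping that put 40 min replicate 1 with 80 min replicates 1 and 2), and for genes called at all 3 times 2 of 100 (2, 4).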

How the results depend on the processing

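The voom, adjusted-deviance, zero-free, log2 CPM and 2-library alternatives, and weights between times, were chosen after seeing the data. Calls of single genes kept their direction under every alternative and often lost their test. Over 822 alternative values of the 36 calls of named genes, 460 stayed below an adjusted p of 0.05, 362 did not and 0 turned. Of 1231 values of the 54 uncalled results, 116 passed. All 36 list calls against control were lost with an estimated correlation, 20 without control replicate 3, 17 without 80 min replicate 1 and 0 with DESeq2's size factors, and 0 turned. Between times, the ribosomal list at 80 against 40 min turned down without 40 min replicate 2 (adjusted p = 0.627), 80 min replicate 1 (0.952) and 80 min replicate 2 (0.881), with a range of 2.9e-09 to 0.952 without each library, and the cause was not tested.

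Counts of genes are given in the order 20, 40 and 80 min against control, with edgeR values of 7, 26 and 3. Sample-quality weights gave 4488, 262 and 5960, DESeq2 1206, 566 and 860, and leaving out 20 min replicate 2 with 80 min replicate 3 gave 2404, 249 and 1631. The replicate block gave 0, 0 and 1 and lost all 36 calls of named genes. Fits of the groups compared gave 3 at 20 min and 1 at 40 min from fewer samples, and also lost all 36. The stricter filter gave 20 at 20 min and 5 at 80 min with 18014 genes tested, no filter 10 at 80 min with 33388, and genes without a 0 gave 13 at 20 min and 9 at 80 min with 24542. Adjusted deviances gave 23 at 20 min and 11 at 80 min, and voom 12 at 80 min. Between times (40 against 20, 80 against 40, 80 against 20 min; 0 with edgeR), weights gave 4963, 1196 and 9360, DESeq2 1439, 248 and 2060, the 2 libraries left out 3140, 669 and 5227, and the groups compared 3 and 1 in the first 2. Voom gave 1 and adjusted deviances 1 at 80 against 40 min, and 3 and 7 at 80 against 20 min. The cause was not tested.

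For the F test (21), the values were 35 with the stricter filter, 0 with the replicate block, 10650 with weights, 91 with adjusted deviances, 4473 without the 2 libraries, 33 for genes without a 0 and 2313 with DESeq2. For genes called at all 3 times (2), they were 0 with the block, 112 with weights, 38 without the 2 libraries, 1 for genes without a 0, 134 with DESeq2 and 0 in fits of the groups compared. The calls shared with the authors' deposited table became 1205, 565 and 857 with DESeq2. Correlations without the 2 libraries were 0.393, 0.374 and 0.486. Lists passing (9, 9 and 18) were 0, 0 and 0 with an estimated correlation, 4 at 20 min without the 2 libraries, and, at 40 min, 15 with members below the stricter filter left out and 3 on log2 CPM. The cause was not tested.

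Leaving out each library in turn, counts ranged from 0 to 1014, 0 to 156 and 0 to 462 against control, 0 to 1450, 0 to 182 and 0 to 3541 between times, 1 to 997 for the F test and 0 to 10 for genes called at all 3 times. Correlations ranged from 0.392 to 0.650, 0.343 to 0.637 and 0.486 to 0.737, and lists passing from 4 to 15, 1 to 11 and 4 to 20. Where this left an arm with 2 plants, the spread was pooled over all groups.

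Groups of 3 plants with a common dispersion of 0.449 limit the test: of simulated genes changed 4-fold, edgeR recovered 19 of 50. The replicate number pairs no samples, since the 18 pairs of libraries that share a number had a median correlation of 0.0126 and the other 36 a median of -0.00494, so the replicate block takes degrees of freedom without a known pairing. DESeq2 called 117 unchanged genes in the simulation at 20 min. The alternatives for FPKM and its pseudocount were not run, as counts were used.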

Other observations

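The members named here were chosen after their values were seen, from lists that did not pass camera. At 20 min, 4 MYB factors were up when adjusted over the list alone, among them Lalb_Chr15g0076591 at 296 ± 148 CPM against 68.4 ± 5.07 CPM in the controls (SD, n = 3; log2 fold change 2.11, SE 0.43, edgeR adjusted p = 0.162 over all genes). Jasmonate genes had 2 members up and 3 down in the same sense. A TIFY protein (Lalb_Chr12g0200271), of a family that represses jasmonate responses, had a log2 fold change of 2.45 (SE 0.58), and the lipoxygenase Lalb_Chr24g0396541, of a family that starts jasmonate synthesis, -2.99 (SE 0.42). At 80 min, a cytokinin dehydrogenase (Lalb_Chr07g0180871), which degrades cytokinin, stood at 6.94 ± 5.32 CPM against 91.5 ± 11.7 CPM in the controls (-3.72, SE 0.50, edgeR adjusted p = 0.0576 over all genes, 0.000755 adjusted over the list alone).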
